A study of Homo sapiens with 36 samples.

How the data were processed

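The starting point was the deposited table of gene counts, which per the file headers the authors made with featureCounts v2.0.0 on paired reads, with the Ensembl release 99 annotation of GRCh38, fragments of 20 to 5000 bases, both mates required to map, primary alignments only and no strand. The submitters' processing notes name STAR, featureCounts, DESeq2 and hg38, without the aligner's version. Per the labels' protocols, LNCaP cells grew in RPMI 1640 with 10% fetal bovine serum, RNA came from the Qiagen AllPrep kit, 1 µg went into TruSeq libraries, and paired reads of 150 bases were made on an Illumina HiSeq. Reads were not analysed here. The table held 60676 genes, of which 60357 matched a symbol in a table of gene names, and these carried 99.9% of the counts. Because reads were counted without strand, reads over exons that 2 genes share on opposite strands were open to loss, and reads of an overlapping gene could count for a named one. The levels of named genes that share exon bases with another gene with counts are uncertain for this reason, and some of the partners are given beside them. These genes were AFF3, ATAD2, BIRC3, BRCA1, CCDC141, CCN3, CDC45, CDCA3, CDKN1A, CENPA, CYP11A1, DDIT3, DEGS2, DOK3, E2F8, FAXDC2, FEN1, HPGD, IRF1, KANK3, KIF20A, KITLG, LDHB, MDM2, MYC, NOP16, PARP2, PLK1, PMEPA1, RAD54L, RDH10, RFC4, SESN1, SULF2, TAF10, TIGAR, TNC, TP53I3, TRIM22, TSC22D3 and UGT2B11.

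All 36 libraries entered 1 edgeR quasi-likelihood fit with a mean for each of the 12 groups, TMM scaling, no block and the filterByExpr filter by group, which left 15744 genes holding 99.8% of the counts. The fit had 24 residual degrees of freedom and a biological coefficient of variation of 6.44%. All groups shared 1 estimate of the spread per gene, so errors can be too small where a group varied more, as DMSO at 72 h did. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in that contrast, and every adjusted p of a gene comes from this edgeR test. The 23 contrasts were each treatment against DMSO at the same hour, the combination against each single drug, the departure of the combination from the sum of both single-drug log2 fold changes, the change of each effect from 8 h to 72 h, and the DMSO cultures over time. The error beside a log2 fold change is its standard error, the absolute log2 fold change over the square root of F. Levels are TMM-scaled CPM, as the mean with the standard deviation over 3 cultures. Where a group had no count, a least fold was set against a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio of counts is given with a 95% interval. These floors and intervals cover counting error only.

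The genes named were fixed by a rule. Against DMSO, the 8 strongest rises and 8 strongest falls by log2 fold change were eligible, and in other contrasts 5 of each. Each needed an adjusted p below 0.05, an ordinary symbol, a mean of at least 1 CPM and, in comparisons of 2 groups, groups that did not overlap. Departures and changes between hours had no such condition on overlap. Up to 4 called members of each list per contrast were eligible too, by size of log2 fold change. The check genes KLK3, TMPRSS2, FKBP5, CDKN1A, MDM2, PARP1, PARP2, MYC and MKI67 were always eligible. The text names fewer of them, from the top of each order, and a few eligible genes are not reported here.

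The lists, contrasts, filters, tests and alternatives were chosen before the data were examined, apart from those stated otherwise. The 19 gene lists were androgen-induced genes, androgen-repressed genes, steroid receptors, p53 target genes, homologous recombination genes, PARP, base excision and end joining genes, DNA replication genes, mitotic genes, interferon-stimulated genes, NF-kB and secretory genes, cholesterol synthesis genes, fatty acid synthesis genes, unfolded protein and amino acid response genes, MYC and ribosome biogenesis genes, hypoxia and glycolysis genes, neuroendocrine genes, luminal identity genes, basal, stromal, endothelial and blood markers, and replication-dependent histones. They were written from general knowledge of these pathways. The steroid receptors had 2 measured members and were left out of the list tests, which needed 5. The other 18 lists were tested in 18 contrasts with limma camera on voom values, with the correlation between genes estimated for each list, and adjusted by Benjamini-Hochberg over all 324 tests. Adjusted p values of lists in the text come from this test. A camera test with a preset correlation of 0.01 was an alternative. A self-contained test, fry, was a second alternative. It asks whether the members moved in a shared direction, not whether they moved more than other genes. Counts of members adjusted over the list alone use only the p values of that list's members.

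The correlation across genes of a drug's effect without and with the other drug used groups that shared no library, the drug against DMSO and the combination against the other drug. Counts and named genes were also computed with RLE scaling, DESeq2, no filter, a filter of 1 CPM in 6 libraries, the replicate number as a block, the sequencing lane as a block, a fit of only the libraries compared, and each replicate left out in turn. A fit without 3 libraries that stood apart was added after the data were seen, and these were picked without a stated cutoff. Labels were also exchanged within each comparison, with 10 divisions for comparisons of 2 groups and 100 for the others, each fitted on only the libraries compared.

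Counts were simulated from the real library sizes, with 1 mean and 1 dispersion per gene for all libraries and a change put in 1 group. They held no other drug effect and no noisier group, so rates in the real data can differ. For the simulated enzalutamide comparison at 24 h, with 15495 genes tested, 80.0% of 50 genes changed by a log2 of 0.5 were recovered and 87.8% of 49 changed by 1, and 7 of 180 calls were unchanged genes. For a simulated departure from the sum at 72 h, with 15491 genes tested, 22.0% of 50 genes changed by a log2 of 0.5 were recovered and 63.3% of 49 changed by 1, and 9 of 137 calls (6.57%) were unchanged genes. For a simulated change of the olaparib effect between 8 h and 72 h, with 15467 genes tested, 36.7% of 49 genes changed by a log2 of 0.5 and 73.5% of 49 changed by 1 were recovered, and 7 of 141 calls were unchanged genes. A planted list of 30 genes moved by a log2 of 0.3 gave a camera p of 8.5e-12, and 1 of 50 random lists fell below 0.05. Genes were drawn independently of each other, so this does not test how camera handles correlation between genes. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.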

Results

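The data were gene counts from LNCaP prostate cancer cells given DMSO, 3 µM enzalutamide, 3 µM olaparib or both drugs for 8, 24 or 72 h, with 3 cultures in each of 12 groups. The 36 libraries held 4.15 to 15.4 M counts, with a median of 9.63 M, and the lowest correlation between replicates was 0.978. The libraries were spread over 3 lanes, 1 of each group per lane, with median totals of 10.0, 6.08 and 11.7 M counts. The first principal component held 24.4% of the variance and the second 9.22%.

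What the androgen pathway inhibitor changed was asked first, by enzalutamide against DMSO at each hour. At 8 h, the solute carrier gene SLC45A3 fell from 250 ± 22.5 to 62.8 ± 1.43 CPM (3 cultures each, adjusted p 4.2e-21), the membrane protease gene TMPRSS2 by a log2 fold change of 1.98 ± 0.06 (adjusted p 9.9e-25) and KLK3, which encodes prostate-specific antigen, by 0.88 ± 0.10 (adjusted p 4.3e-08). CHRNA2, a nicotinic receptor subunit gene, fell from 14.6 ± 4.20 to 2.91 ± 0.771 CPM (-2.34 ± 0.19, adjusted p 1.8e-11). ABCA1, a cholesterol exporter gene, rose from 1.36 ± 0.301 to 4.24 ± 1.18 CPM (1.61 ± 0.24, adjusted p 1.4e-05), and the phospholipase gene PLD1 rose by 1.57 ± 0.38 (adjusted p 0.011). PLD1 lost its call with 2 of the libraries left out.

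The androgen-induced genes led the response at 8 h. Of 43 measured, 23 fell, 1 rose and 19 were not called, or 31 and 2 called when adjusted over the list alone, with a list median of -0.66 (adjusted p 3.2e-11). PMEPA1, a TGF-beta pathway gene, fell by 1.72 ± 0.08. Of 13 androgen-repressed genes, OPRK1, an opioid receptor gene, rose by 1.26 ± 0.31 (adjusted p 0.012). This list was called higher with an adjusted p of 0.042. Of 48 DNA replication genes 3 fell, among them ATAD2 by 0.28 ± 0.06, and the list was lower with a median of -0.11 (adjusted p 0.0082). Among 38 p53 target genes 5 rose, including SESN1 by 0.61 ± 0.08, and 1 fell, and the list was not called (adjusted p 0.16). SLC7A5, an amino acid transporter gene, rose by 0.66 ± 0.09 (adjusted p 6.6e-06). In all, 171 genes rose and 305 fell, 476 of 15744, of which 65 changed at least 2-fold. Without DMSO 8 h replicate 2 the count was 282.

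At 24 h the falls of androgen-induced genes were larger. KLK3 fell from 714 to 91.0 CPM (-2.98 ± 0.11, 3 cultures each, adjusted p 8.2e-23) and its neighbour and near relative KLK2, at 50861568 to 50880567 on chromosome 19 of GRCh38, from 326 ± 33.3 to 32.1 ± 4.65 CPM (-3.34 ± 0.10, adjusted p 2.2e-25). CHRNA2 fell from 16.8 ± 2.25 to 0.410 ± 0.0953 CPM (-5.28 ± 0.25, adjusted p 6.7e-19) and the cold-sensing channel gene TRPM8 by 4.17 ± 0.26 (adjusted p 1.2e-15). PLD1 rose from 0.306 ± 0.103 to 2.75 ± 0.539 CPM (3.11 ± 0.39, adjusted p 8.1e-08), the potassium channel gene KCNU1 by 2.87 ± 0.36 (adjusted p 1.2e-07) and the amino acid transporter gene SLC6A20 by 2.86 ± 0.34 (adjusted p 4.6e-08). Of the 43 androgen-induced genes 35 fell and 1 rose (list median -0.95, adjusted p 3.0e-10). Of the 13 androgen-repressed genes 10 rose and none fell, among them UGT2B15, which encodes a steroid-conjugating enzyme, by 1.38 ± 0.11 (list median 0.71, adjusted p 2.4e-04).

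Genes of cell division fell at 24 h. Of 48 DNA replication genes 45 fell and none rose, 46 when adjusted over the list alone (list median -0.59, adjusted p 9.7e-08). The transcription factor gene E2F2 fell by 0.95 ± 0.12, the clamp loader gene RFC3 by 0.91 ± 0.09 and the flap nuclease gene FEN1, whose exons overlap FADS2, by 0.81 ± 0.07. Of 41 mitotic genes 36 fell, among them the kinase gene AURKB by 0.79 ± 0.09 and MYBL2 by 0.73 ± 0.05 (list median -0.45, adjusted p 2.6e-05). MKI67, a proliferation marker, fell by 0.61 ± 0.11 (adjusted p 3.9e-05). Of 43 homologous recombination genes 23 fell and 1 rose, including RAD54L by 0.75 ± 0.09 and RAD51AP1 by 0.64 ± 0.11 (list median -0.31, adjusted p 9.5e-04). Of 25 PARP, base excision and end joining genes 8 fell and 1 rose, PARP1 by 0.22 ± 0.06 (adjusted p 0.011) and PARP2 by 0.34 ± 0.06 (adjusted p 9.4e-05). This list was lower with an adjusted p of 0.046, and was not called with RLE scaling. Replication-dependent histones rose in 6 of 9, with H4C8 at 0.53 ± 0.11 (adjusted p of the list 0.0072).

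Lipid genes fell and stress genes rose at 24 h. Of 22 cholesterol synthesis genes 16 fell and 1 rose, including INSIG1 by 0.70 ± 0.06 (adjusted p of the list 4.9e-06). Of 15 fatty acid synthesis genes 10 fell and 1 rose, with the elongase gene ELOVL7 lower by 1.87 ± 0.09 and the synthase gene FASN by 0.55 ± 0.09 (adjusted p 0.0025). Of 26 unfolded protein and amino acid response genes 16 rose and none fell, with DDIT3, whose exons overlap MARS1, at 0.75 ± 0.10, SLC7A5 at 0.70 ± 0.09 and the chaperone gene HSPA5 at 0.43 ± 0.06 (adjusted p 0.0071). Of the p53 target genes 10 rose and 3 fell (list median 0.12, adjusted p 0.042), while CDKN1A, a cyclin-dependent kinase inhibitor gene, was not called (0.12 ± 0.06, adjusted p 0.17). In all, 1293 genes rose and 1667 fell, 279 of them at least 2-fold.

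At 72 h KLK3 stood at 7.25 CPM against 745 CPM in DMSO (-6.67 ± 0.14, 3 cultures each, adjusted p 1.9e-30) and KLK2 at 2.96 ± 0.423 against 322 ± 10.8 CPM (-6.77 ± 0.15, adjusted p 1.9e-30). The sialyltransferase gene ST6GALNAC1 fell from 19.8 ± 1.77 to 0.3 ± 0.235 CPM (-6.13 ± 0.27, adjusted p 2.4e-20). PLA2G5, a secreted phospholipase gene, had no count after enzalutamide and was at least 20.9-fold lower than its 2.22 ± 0.132 CPM in DMSO. HPGD, which encodes a prostaglandin dehydrogenase, had 2 counts, 49.3-fold below DMSO (13.2 to 413 by counting error). AOC1, a diamine oxidase gene, rose from 0.217 ± 0.0856 to 5.84 ± 0.775 CPM (4.54 ± 0.36, adjusted p 6.8e-13), the matrix gene TNC, which shares exons with DELEC1, by 3.91 ± 0.51 (adjusted p 1.3e-07) and CCDC80 by 3.67 ± 0.40 (adjusted p 3.3e-09). The steroid receptors had 2 measured members, and of these the progesterone receptor gene PGR rose from 0.475 ± 0.154 to 3.46 ± 0.381 CPM (2.94 ± 0.37, adjusted p 7.7e-08).

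Of the androgen-induced genes 37 fell and 2 rose at 72 h (list median -1.46, adjusted p 3.8e-10), and of the androgen-repressed genes 12 of 13 rose, with CCN3 at 3.09 ± 0.54 and UGT2B15 at 2.37 ± 0.11 (list median 1.87, adjusted p 3.2e-06). Unfolded protein and amino acid response genes, higher at 24 h, fell in 23 of 26 at 72 h, with TRIB3 lower by 1.11 ± 0.07, CHAC1 by 1.05 ± 0.11 and DDIT4 by 0.96 ± 0.09 (adjusted p 6.3e-05). Of 26 MYC and ribosome biogenesis genes 20 fell and none rose, including NOP16 by 0.67 ± 0.09 and MYC by 0.53 ± 0.05 (adjusted p 0.017). Of 9 NF-kB and secretory genes 5 fell, including IL32 by 1.37 ± 0.18 and NFKB2 by 0.86 ± 0.08 (adjusted p 0.0029). Cholesterol synthesis genes fell in 14 of 22 (adjusted p 1.7e-05) and fatty acid synthesis genes in 10 of 15, with ELOVL7 lower by 3.15 ± 0.11 (adjusted p 0.0028). The hexokinase gene HK2 fell by 1.21 ± 0.11 among 11 falls and 2 rises of 23 hypoxia and glycolysis genes, a list that was not called (adjusted p 0.49). Against DMSO at 8 h, the mean log2 CPM of this list was higher by 0.281 (SE 0.0532) in DMSO at 72 h. With enzalutamide it was higher by 0.273 (SE 0.0629) at 8 h and by 0.00884 (SE 0.0422) at 72 h. A rise in the DMSO cultures was not separated from a fall with the drug.

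The cell division lists were not called at 72 h of enzalutamide. Of the DNA replication genes 15 fell and 1 rose (list median -0.15, adjusted p 0.16), of the mitotic genes 5 rose and 2 fell (median -0.01, adjusted p 0.72), and of the homologous recombination genes 2 fell and 1 rose (adjusted p 0.81). MKI67 was not called (0.12 ± 0.11, adjusted p 0.44). The p53 target genes were split, with 17 lower, 6 higher and 15 not called (adjusted p 0.27). GDF15, a stress cytokine gene, fell by 1.51 ± 0.10 and CDKN1A by 0.35 ± 0.06 (adjusted p 3.5e-05), while the growth factor gene KITLG rose by 1.35 ± 0.15. Luminal identity genes moved both ways and were not called, with KRT19 lower by 2.32 ± 0.40, SPDEF lower by 0.96 ± 0.07 and CD24 higher by 1.14 ± 0.17. In all, 1996 genes rose and 2291 fell, 596 at least 2-fold. A fit of only the libraries compared called 1956. DMSO 72 h replicate 1 had 4.66 M counts and 1.54% of them from mitochondrial genes, against 5.56% and 3.97% in the other DMSO cultures of that hour.

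**Figure D1:**
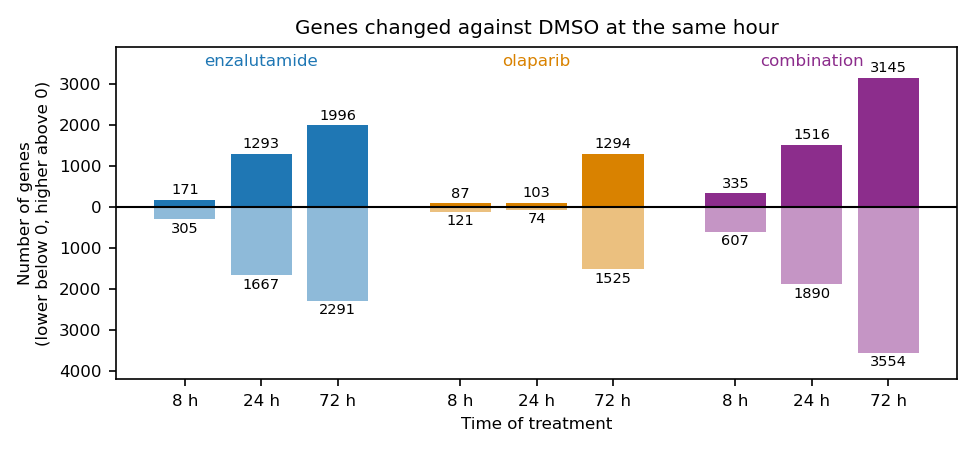
Genes higher (above 0) and lower (below 0) than DMSO at the same hour at an adjusted p below 0.05 in edgeR, of 15744 tested, with 3 cultures per group.

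What PARP inhibition changed alone was asked by olaparib against DMSO. At 8 h CDKN1A rose from 421 to 967 CPM (1.20 ± 0.06, 3 cultures each, adjusted p 1.4e-16), TP53I3, an oxidoreductase gene that shares exons with FAM228B, by 1.22 ± 0.19 (adjusted p 1.0e-04), BBC3, an apoptosis gene, by 0.87 ± 0.13 (adjusted p 3.3e-05) and MDM2, which encodes the ubiquitin ligase of p53, by 0.46 ± 0.06 (adjusted p 1.5e-05). FAXDC2, which shares exons with CNOT8, rose from 1.29 ± 0.837 to 6.66 ± 0.647 CPM (2.16 ± 0.24, adjusted p 1.4e-07). CDC20, an activator of the anaphase ligase, fell from 127 ± 7.16 to 64.3 ± 0.386 CPM (-0.98 ± 0.06, adjusted p 4.9e-14) and the mitotic kinase gene PLK1 from 181 ± 8.09 to 94.1 ± 2.73 CPM (-0.94 ± 0.07, adjusted p 9.0e-12). CRLS1, a cardiolipin synthase gene, rose by 2.36 ± 0.33 (adjusted p 1.3e-05), and it also rose by 2.94 ± 0.29 in DMSO cultures between 8 h and 24 h.

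Of 38 p53 target genes 13 rose and none fell at 8 h of olaparib, 23 when adjusted over the list alone (list median 0.25, adjusted p 3.5e-08). Of 41 mitotic genes 30 fell and none rose, 38 when adjusted over the list alone, with AURKA lower by 0.72 ± 0.10 (list median -0.46, adjusted p 2.5e-08). DNA replication genes were lower with 2 called, TK1 by 0.35 ± 0.06 and ATAD2 by 0.25 ± 0.06 (adjusted p 0.017), and ATAD2 lost its call in a fit of only the libraries compared. Of the androgen-induced genes 1 was called, and no homologous recombination gene or PARP, base excision and end joining gene was. In all, 87 genes rose and 121 fell. The count of 208 moved with single libraries, to 104 without olaparib replicate 2, 107 without DMSO replicate 2 and 111 without DMSO replicate 1, and it was 72 in a fit of only the libraries compared and 428 with no filter. Without the 3 libraries that stood apart, a set chosen after the data were seen, it was 401, of which 57.6% were higher against 41.8% in the full set.

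At 24 h CDKN1A reached 1437 against 404 CPM (1.83 ± 0.06, 3 cultures each, adjusted p 9.9e-23), TP53I3 21.2 ± 0.695 against 3.40 ± 1.55 CPM (2.69 ± 0.17, adjusted p 4.3e-14) and MDM2 rose by 0.72 ± 0.06 (adjusted p 2.2e-10). FAXDC2 rose from 1.36 ± 0.207 to 10.2 ± 1.13 CPM (2.88 ± 0.21, adjusted p 3.0e-12) and the sulfatase gene SULF2, which shares exons with NCOA3, from 0.562 ± 0.0287 to 3.89 ± 1.13 CPM (2.73 ± 0.32, adjusted p 3.6e-07). Of the p53 target genes 29 of 38 rose and none fell, 35 when adjusted over the list alone, with KITLG at 1.15 ± 0.16 and the antiproliferation gene BTG2 at 1.13 ± 0.06 (list median 0.50, adjusted p 1.9e-12). Of the mitotic genes 11 fell, 30 when adjusted over the list alone, including CDCA3, which shares exons with GNB3, by 0.63 ± 0.07 and CDC20 by 0.62 ± 0.06 (list median -0.25, adjusted p 7.5e-06). Fatty acid synthesis genes fell in 4 of 15, with FASN lower by 0.45 ± 0.09 (adjusted p 8.6e-04), and cholesterol synthesis genes in 3 of 22, with INSIG1 lower by 0.39 ± 0.06 (adjusted p 7.5e-04). Luminal identity genes were lower with 1 called (adjusted p 0.041) and replication-dependent histones with none (adjusted p 0.038). In all, 103 genes rose and 74 fell. The count of 177 was 100 without DMSO 24 h replicate 1 or olaparib 24 h replicate 2, 103 without olaparib 24 h replicate 3 and 112 without DMSO 24 h replicate 2.

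At 72 h of olaparib the largest list shift was a fall of unfolded protein and amino acid response genes. CHAC1, a glutathione-degrading enzyme gene, fell from 56.1 ± 3.25 to 13 ± 1.71 CPM (-2.09 ± 0.12, 3 cultures each, adjusted p 1.6e-15), SLC7A5 by 1.55 ± 0.12 (adjusted p 3.7e-12), PHGDH, which encodes the first enzyme of serine synthesis, by 1.30 ± 0.08 (adjusted p 5.8e-15) and TRIB3 by 1.22 ± 0.08 (adjusted p 5.8e-15). Of 26 such genes 22 fell and none rose (list median -0.67, adjusted p 5.5e-07). CDKN1A stayed higher at 1173 against 381 CPM (1.62 ± 0.06, adjusted p 7.4e-21) and MDM2 at 209 against 118 CPM (0.83 ± 0.06, adjusted p 1.7e-12). SULF2 rose by 2.82 ± 0.33 (adjusted p 4.8e-08), the cytidine deaminase gene APOBEC3H by 2.42 ± 0.37 (adjusted p 9.4e-06) and TRIM22 by 2.39 ± 0.42 (adjusted p 7.1e-05). The complement regulator gene CD55 fell from 4.33 ± 1.12 to 0.928 ± 0.195 CPM (-2.21 ± 0.28, adjusted p 3.2e-07).

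Androgen-induced genes were higher at 72 h of olaparib. Of 43, 18 rose and 3 fell, with the transcription factor gene MAF at 1.73 ± 0.09, the kinase gene SGK1 at 1.32 ± 0.18 and FKBP5 at 0.36 ± 0.06 (adjusted p 8.6e-05), and TSC22D3 lower by 1.24 ± 0.08 (list median 0.19, adjusted p 0.0013). KLK3 was not called (-0.24 ± 0.10, adjusted p 0.082). Of the p53 target genes 32 rose and 1 fell, with TIGAR at 1.24 ± 0.19 (adjusted p 7.2e-09). Mitotic genes fell in 15 of 41 and rose in 1 (adjusted p 0.024), and DNA replication genes fell in 15 of 48 (adjusted p 0.033). Replication-dependent histones rose in 5 of 9 and fell in 1, with H2BC21 at 0.86 ± 0.09 and H4C8 at 0.82 ± 0.12 (adjusted p 0.0025). NF-kB and secretory genes rose in 5 of 9 and fell in 1, with BIRC3 at 0.63 ± 0.16 and IL32 at 0.60 ± 0.15 (adjusted p 0.040). Homologous recombination genes were split, 3 higher and 3 lower of 43. PARP1 was not called (-0.17 ± 0.06, adjusted p 0.059). In all, 1294 genes rose and 1525 fell, 265 at least 2-fold. This count of 2819 was 1829 without olaparib 72 h replicate 1 and 639 in a fit of only the libraries compared.

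**Figure D2:**
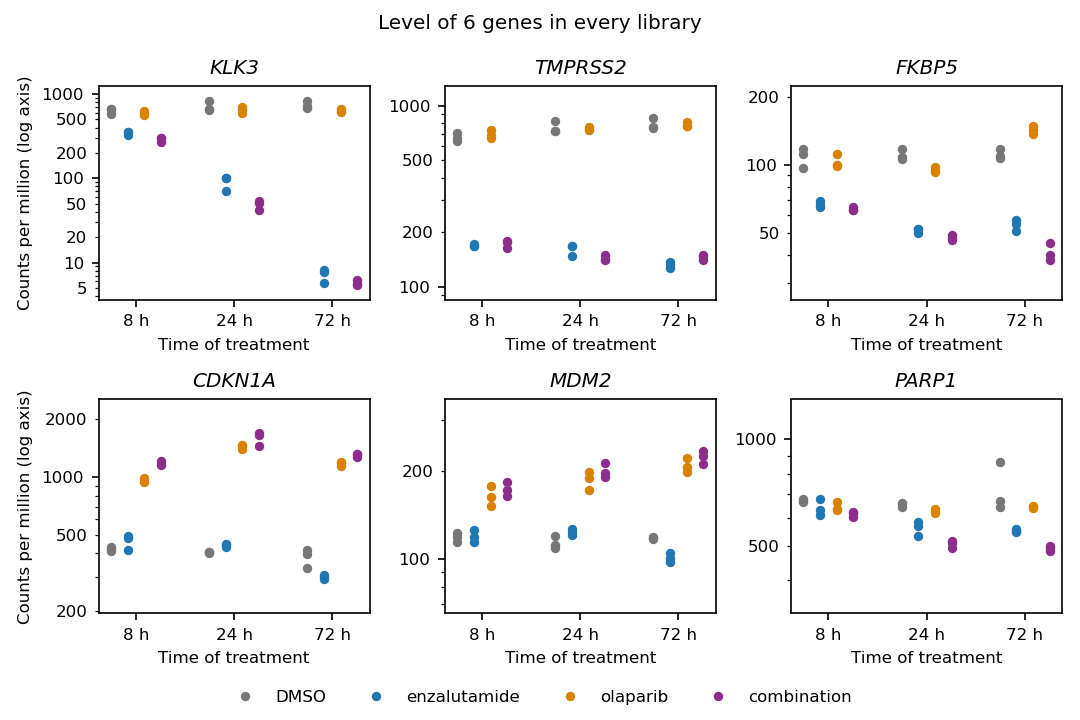
CPM of 6 genes in each of 36 libraries on a log axis, 1 point per culture, by treatment and hour.

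What both drugs did together was asked against DMSO. At 8 h CHRNA2 fell by 2.95 ± 0.22 (3 cultures each, adjusted p 4.6e-13), while CDKN1A rose to 1179 CPM (1.49 ± 0.06, adjusted p 2.7e-20) and CDC20 fell by 1.08 ± 0.06 (adjusted p 2.9e-16). Of the androgen-induced genes 27 fell and 1 rose (adjusted p 2.5e-10), of the p53 target genes 23 rose and none fell (list median 0.41, adjusted p 2.5e-08) and of the mitotic genes 36 of 41 fell, with KIF20A, which shares exons with BRD8 and CDC23, lower by 0.96 ± 0.07. DNA replication genes fell in 11 of 48 (adjusted p 0.0048), cholesterol synthesis genes in 4 of 22 (adjusted p 0.0029), and MYC and ribosome biogenesis genes in 8 of 26 with NOP56 lower by 0.33 ± 0.05 (adjusted p 0.040). The androgen-repressed genes were not called (adjusted p 0.12). In all, 335 genes rose and 607 fell, 102 at least 2-fold, and the count of 942 was 595 without DMSO 8 h replicate 2.

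At 24 h of both drugs KLK3 stood at 49.2 CPM (-3.85 ± 0.12, adjusted p 1.4e-25), CDKN1A at 1600 CPM (1.98 ± 0.06, adjusted p 1.1e-24) and RDH10, a retinol dehydrogenase gene, rose from 17.1 ± 1.47 to 72.2 ± 4.14 CPM (2.07 ± 0.08, 3 cultures each, adjusted p 3.7e-21). The desmosome gene PKP1 had no count and was at least 18.6-fold lower. KCNU1 rose by 3.58 ± 0.35 (adjusted p 2.3e-10) and PGR by 2.29 ± 0.40 (adjusted p 3.4e-05). Androgen-induced genes fell in 38 of 43 and rose in 2 (adjusted p 5.1e-10), androgen-repressed genes rose in 9 of 13 (adjusted p 5.3e-04) and p53 target genes in 32 of 38 (adjusted p 2.5e-08). DNA replication genes fell in 44 of 48, with CDC45 lower by 0.90 ± 0.12 (adjusted p 6.3e-07), and mitotic genes in 40 of 41, with KIF20A lower by 1.10 ± 0.07. Homologous recombination genes fell in 19 and rose in 2 of 43 (adjusted p 0.0030). PARP, base excision and end joining genes fell in 7 and rose in 1 of 25 (adjusted p 0.049), a call that RLE scaling ended. Cholesterol synthesis genes fell in 16 of 22 (adjusted p 4.7e-07) and fatty acid synthesis genes in 12 of 15 (adjusted p 9.9e-05). In all, 1516 genes rose and 1890 fell, 340 at least 2-fold.

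At 72 h of both drugs 3145 genes rose and 3554 fell, 1120 of them at least 2-fold. KLK3 stood at 5.77 CPM (-6.98 ± 0.15, 3 cultures each, adjusted p 5.0e-30). TNC rose from 0.214 ± 0.193 to 4.79 ± 1.19 CPM (4.77 ± 0.46, adjusted p 9.8e-11) and MID1, a ubiquitin ligase gene, from 2.36 ± 0.733 to 34.8 ± 2.61 CPM (3.78 ± 0.16, adjusted p 2.4e-21). All 48 DNA replication genes fell, with UHRF1 lower by 1.11 ± 0.12 and RFC4 by 1.09 ± 0.11 (list median -0.68, adjusted p 1.3e-05), and 39 of 41 mitotic genes fell, with MYBL2 and CENPA each lower by 1.23, with errors of 0.06 and 0.17 (adjusted p 2.5e-04). Homologous recombination genes fell in 23 and rose in 2 of 43, including RAD51AP1 by 0.95 ± 0.13 and BRCA1 by 0.76 ± 0.09 (adjusted p 0.040), and this list call was lost without the 3 libraries that stood apart. Of PARP, base excision and end joining genes 11 fell and 2 rose (adjusted p 0.098), with PARP1 lower by 0.55 ± 0.06 (adjusted p 3.6e-09). PARP1 stood at 865 CPM in DMSO 72 h replicate 1 against 643 and 668 CPM in the other DMSO cultures, which enlarged this fall. All combination cultures lay lower, at 484 to 501 CPM. A fit of only the libraries compared called 4199 genes rather than 6699.

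All 26 unfolded protein and amino acid response genes fell at 72 h of both drugs, with CHAC1 lower by 2.22 ± 0.13 and SLC7A5 by 1.68 ± 0.13 (list median -0.78, adjusted p 3.8e-05). Androgen-induced genes fell in 38 of 43 (adjusted p 1.9e-08) and androgen-repressed genes rose in 12 of 13 (list median 2.20, adjusted p 1.7e-05). The p53 target genes rose in 29 of 38 and fell in 1, with KITLG at 2.00 ± 0.15 and SESN1 at 1.94 ± 0.08 (adjusted p 8.6e-06). Cholesterol synthesis genes fell in 18 of 22, with INSIG1 lower by 1.58 ± 0.07 (adjusted p 7.3e-06), fatty acid synthesis genes in 13 of 15, with FASN lower by 1.20 ± 0.09 (adjusted p 7.1e-05), and MYC and ribosome biogenesis genes in 22 of 26 (adjusted p 0.030). Replication-dependent histones rose in 6 of 9, with H4C8 at 1.38 ± 0.11 (adjusted p 0.0075). Hypoxia and glycolysis genes fell in 13 and rose in 4 of 23 without a call (adjusted p 0.49), with HK2 lower by 1.60 ± 0.11. Against DMSO at 8 h, their mean log2 CPM was lower by 0.147 (SE 0.0382) with both drugs and higher by 0.281 (SE 0.0532) in DMSO at 72 h.

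A few lists were never called against DMSO. Interferon-stimulated genes, 26 measured, rose in 10 and fell in 5 at 72 h of both drugs, with IRF1 at 1.00 ± 0.15 and ISG20 lower by 0.80 ± 0.17, and were not called in any contrast, as was the case for hypoxia and glycolysis genes. Neuroendocrine genes had 6 measured members and were not called, with an adjusted p of 0.096 at 72 h of olaparib, where EZH2 fell by 0.41 ± 0.08. The 7 measured basal, stromal, endothelial and blood markers were called once, higher in the combination against enzalutamide at 24 h with no member called (adjusted p 0.042), and not without the 3 libraries that stood apart.

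**Figure D3:**
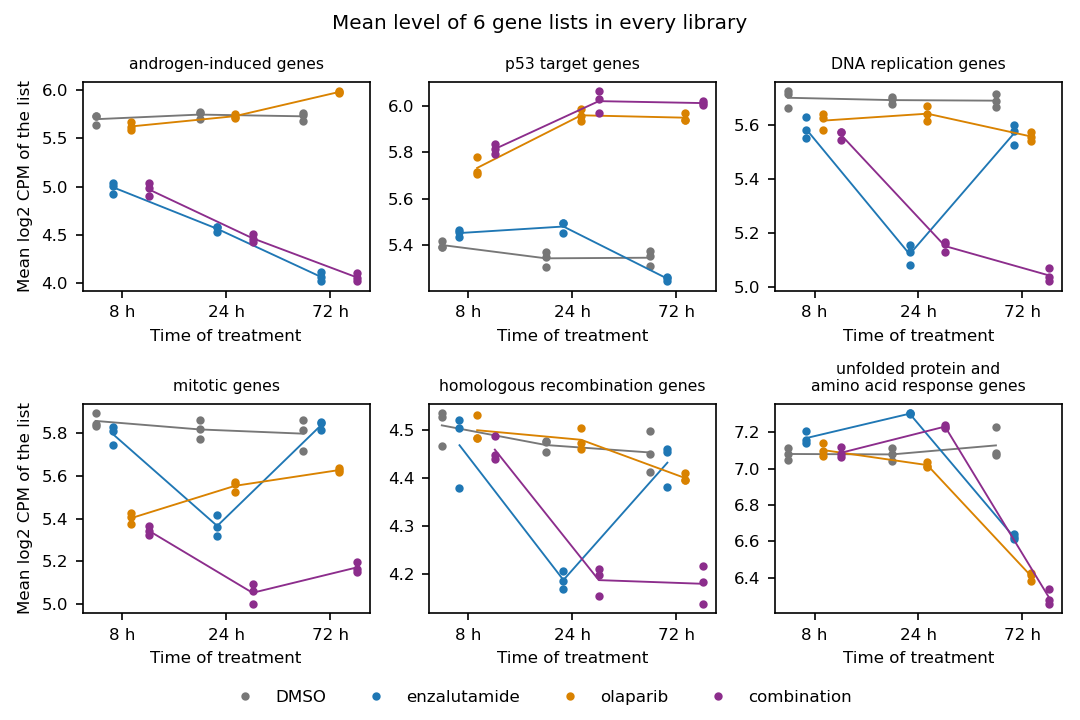
Mean log2 CPM of 6 gene lists in each library (points) and their group means (lines) over time, with 3 cultures per group.

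What olaparib added to enzalutamide was asked by the combination against enzalutamide. At 8 h CDKN1A rose by 1.35 ± 0.06 (3 cultures each, adjusted p 2.4e-18), TP53I3 from 3.40 ± 0.672 to 11.4 ± 1.25 CPM (1.75 ± 0.19, adjusted p 7.2e-08) and FAXDC2 by 2.26 ± 0.25 (adjusted p 1.1e-07), while CDC20 fell from 119 ± 2.11 to 59.9 ± 1.77 CPM (-0.99 ± 0.06, adjusted p 2.8e-14). Of the p53 target genes 15 rose (adjusted p 5.5e-10) and of the mitotic genes 28 fell, with no member of either moving the other way. Cholesterol synthesis genes were lower with no member called (adjusted p 0.019), a call lost without the 3 libraries that stood apart, and unfolded protein and amino acid response genes likewise had none called (adjusted p 0.032). There were 37 genes higher and 66 lower, and the count of 103 was 60 without combination 8 h replicate 2 and 174 with no filter.

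At 24 h KLK2 fell from 32.1 ± 4.65 to 17 ± 4.44 CPM (-0.89 ± 0.12, 3 cultures each, adjusted p 1.1e-05) and KLK3 by 0.87 ± 0.11 (adjusted p 3.0e-06) in the combination against enzalutamide, and the androgen-induced list was not called (3 lower, adjusted p 0.11). SULF2 rose by 2.73 ± 0.33 (adjusted p 4.9e-07). Of the p53 target genes 27 rose and of the mitotic genes 19 fell. Cholesterol synthesis genes fell in 3 of 22, 11 when adjusted over the list alone (adjusted p 1.8e-04). Luminal identity genes (adjusted p 0.042) and replication-dependent histones (adjusted p 0.0060) were lower with no member called. There were 170 genes higher and 133 lower. The count of 303 was 121 without combination 24 h replicate 1, 153 without combination 24 h replicate 2 or enzalutamide 24 h replicate 1 and 164 without enzalutamide 24 h replicate 3, and 678 in a fit of only the libraries compared.

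At 72 h SULF2 rose by 3.45 ± 0.30 (3 cultures each, adjusted p 7.7e-11), FAXDC2 from 0.886 ± 0.209 to 9.30 ± 0.913 CPM (3.33 ± 0.24, adjusted p 7.5e-13), CDKN1A by 2.12 ± 0.06 (adjusted p 8.6e-25) and ZMAT3 by 1.44 ± 0.08 in the combination against enzalutamide. Of 38 p53 target genes 36 rose (list median 0.65, adjusted p 2.5e-10). DNA replication genes fell in 43 of 48, with E2F8 lower by 1.00 ± 0.13 (adjusted p 1.3e-07), mitotic genes in 40 of 41, with CENPA lower by 1.19 ± 0.16, and homologous recombination genes in 19 and rose in 1 of 43, with BRCA1 lower by 0.77 ± 0.09 (adjusted p 0.0030). PARP, base excision and end joining genes fell in 5 of 25 (adjusted p 0.041), with PARP2 lower by 0.32 ± 0.07 (adjusted p 5.2e-04). Unfolded protein and amino acid response genes fell in 12 and rose in 1 of 26, with SLC7A5 lower by 1.48 ± 0.13 (adjusted p 0.0016). Androgen-repressed genes rose in 5 of 13, with UGT2B11 at 0.89 ± 0.13 (adjusted p 0.020), while androgen-induced genes were split, 6 higher and 7 lower (adjusted p 0.99), with FKBP5 lower by 0.39 ± 0.07 (adjusted p 1.7e-04). Replication-dependent histones rose in 5 of 9 (adjusted p 3.7e-04). NF-kB and secretory genes rose in 4 of 9 (adjusted p 0.044), not with lane as a block. There were 1017 genes higher and 1266 lower.

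What enzalutamide added to olaparib was asked by the combination against olaparib. At 8 h the transcription factor gene SOX9 rose by 1.18 ± 0.13 (3 cultures each, adjusted p 2.8e-08). At 24 h CHRNA2 fell from 15.4 ± 1.44 to 0.409 ± 0.129 CPM (-5.28 ± 0.30, adjusted p 1.2e-16) and SLC6A20 rose by 3.15 ± 0.40 (adjusted p 1.6e-07). At 72 h KLK2 fell from 330 ± 16.4 to 2.07 ± 0.698 CPM (-7.26 ± 0.16, adjusted p 3.7e-30). CCDC141, which shares exons with TTN, and the olfactory receptor gene OR5B2 had no count in the combination and were at least 20-fold and 16.3-fold lower. OPRK1 rose from 1.04 ± 0.397 to 13.6 ± 2.34 CPM (3.75 ± 0.28, adjusted p 1.0e-13) and ROR2, a WNT receptor gene, from 0.171 ± 0.160 to 2.21 ± 0.227 CPM (adjusted p 2.6e-08).

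Androgen-induced genes fell in 23, 37 and 38 of 43 at 8, 24 and 72 h in the combination against olaparib, with 1 higher each time, and androgen-repressed genes rose in 1, 8 and 13 of 13. The androgen-repressed call at 8 h (adjusted p 0.041) and the cholesterol synthesis call at 8 h (3 lower, adjusted p 0.039) were lost without the 3 libraries that stood apart. The p53 target genes were higher at 8 h with 5 called (adjusted p 0.014) and not called at 24 h (adjusted p 0.33) or 72 h (10 higher, 8 lower, adjusted p 0.46). DNA replication genes fell in 44 of 48 at 24 h and 45 at 72 h, mitotic genes in 40 of 41 at both, and homologous recombination genes in 20 of 43 at 24 h (adjusted p 7.4e-04) and 21 at 72 h (adjusted p 0.040), the latter not without the 3 libraries that stood apart. NF-kB and secretory genes fell in 5 of 9 at 72 h (adjusted p 0.0075) and MYC and ribosome biogenesis genes in 25 of 26 (adjusted p 0.0098). Unfolded protein and amino acid response genes rose in 13 of 26 at 24 h (adjusted p 0.0072) and were not called at 72 h, when 1 rose and 8 fell (adjusted p 0.26). Replication-dependent histones rose in 4 of 9 at 24 h (adjusted p 0.018). There were 345, 2141 and 5391 genes changed at 8, 24 and 72 h, of which 225, 1212 and 2827 were lower.

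Whether a drug moved the same genes without and with the other drug was asked with groups that shared no library. The enzalutamide effects correlated across 15744 genes by 0.305 at 8 h, 0.662 at 24 h and 0.747 at 72 h. At 72 h 1382 genes, KITLG among them, rose with enzalutamide in both settings where 325 were expected from independence, 1536 fell in both where 411 were expected, and 31 were called in opposite directions. At 8 h 75 rose and 174 fell in both, with none opposite, and at 24 h 600 rose and 909 fell, again with none opposite. The olaparib effects correlated by 0.212, 0.227 and 0.455 at 8, 24 and 72 h, and by 0.135 at 8 h without olaparib 8 h replicate 3. At 72 h 444 genes, including CDKN1A and SULF2, rose in both and 585, including SLC7A5 and CHAC1, fell in both, where 83.6 and 123 were expected from independence, and 21 were called in opposite directions. Of the genes called with olaparib alone, 197 of 208 at 8 h, 172 of 177 at 24 h and 2438 of 2819 at 72 h had the same sign in the presence of enzalutamide. Their median ratio of the olaparib effect with enzalutamide to that without was 0.551, 0.710 and 0.521 at 8, 24 and 72 h. These genes were picked by their call without enzalutamide, so the ratio can be low without a real difference.

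Whether the combination departed from the sum of both drugs was asked on the log2 scale. No gene departed at 8 h or 24 h in edgeR, with 681 and 959 genes at a raw p below 0.05, and DESeq2 called 0 genes at both hours. With no filter, 20 and 31 genes were called. At 24 h 6 genes were called without DMSO 24 h replicate 2, 2 without combination 24 h replicate 1 and 1 without enzalutamide 24 h replicate 3. The unfolded protein and amino acid response list was below the sum at 8 h (adjusted p 0.041) and the p53 list at 24 h (adjusted p 0.042).

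At 72 h 356 genes departed, 151 above and 205 below the sum. DDIT3, which encodes a stress transcription factor, was above it by 1.28 ± 0.18 (3 cultures in each of 4 groups, adjusted p 2.1e-05), standing at 24.1 ± 4.92 CPM in DMSO, 13.4 ± 1.21 with enzalutamide, 10.3 ± 1.14 with olaparib and 14.4 ± 2.08 with both, so that it was below DMSO in each drug group. CD55 was above it by 1.73 ± 0.43 (adjusted p 0.020), GDF15 by 0.91 ± 0.14 (adjusted p 9.0e-05) and CDKN1A by 0.51 ± 0.09 (adjusted p 5.7e-04). GDF15 stood at 1234 CPM in DMSO, 431 with enzalutamide, 906 with olaparib and 597 with both, so that it fell less than the sum. FKBP5, which encodes a co-chaperone of steroid receptors, stood at 112 CPM in DMSO, 54.4 with enzalutamide, 143 with olaparib and 41.1 with both, below the sum by 0.75 ± 0.10 (adjusted p 1.4e-05). MAF was below it by 0.89 ± 0.15 (adjusted p 5.3e-04) and AFF3 by 1.81 ± 0.28 (adjusted p 9.4e-05). By the estimates alone, called or not against DMSO, 122 of the 356 moved further than the sum, 91 less far and 143 against its sign. The single-drug estimates differed in sign for 154, which includes estimates near no change. Against DMSO 164 of the 356 were called with enzalutamide, 186 with olaparib, 110 with neither and 276 with the combination.

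Cell division genes fell below the sum at 72 h. Of 48 DNA replication genes 18 were called below and none above, 35 when adjusted over the list alone, with CDC6 lower by 0.71 ± 0.11 and RRM2 by 0.64 ± 0.08 (list median -0.36, adjusted p 1.0e-06). Of 41 mitotic genes 27 were below, 38 when adjusted over the list alone, with AURKA lower by 0.80 ± 0.13 and PLK1 by 0.69 ± 0.10 (list median -0.46, adjusted p 1.0e-06). Homologous recombination genes were below with 3 called, including BRCA1 by 0.57 ± 0.13 (adjusted p 0.0057), cholesterol synthesis genes with 2 (adjusted p 0.0016), fatty acid synthesis genes with 2 (adjusted p 0.020) and androgen-induced genes with 4 below and 1 above (adjusted p 0.0046). Unfolded protein and amino acid response genes were above with 11 called, including CHAC1 by 0.91 ± 0.19 (list median 0.36, adjusted p 5.6e-05), p53 target genes with 6 above and 1 below (adjusted p 0.0045) and androgen-repressed genes with 3 above, including UGT2B17 by 0.97 ± 0.16 (adjusted p 0.0063). The count of 356 was 63 in a fit of only the libraries compared, where CD55 and BRCA1 were not called. It was 193 without olaparib 72 h replicate 1, 202 without combination 72 h replicate 3, 218 without enzalutamide 72 h replicate 1, 234 without enzalutamide 72 h replicate 2, 236 without combination 72 h replicate 2 and 879 without DMSO 72 h replicate 2.

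**Figure D4:**
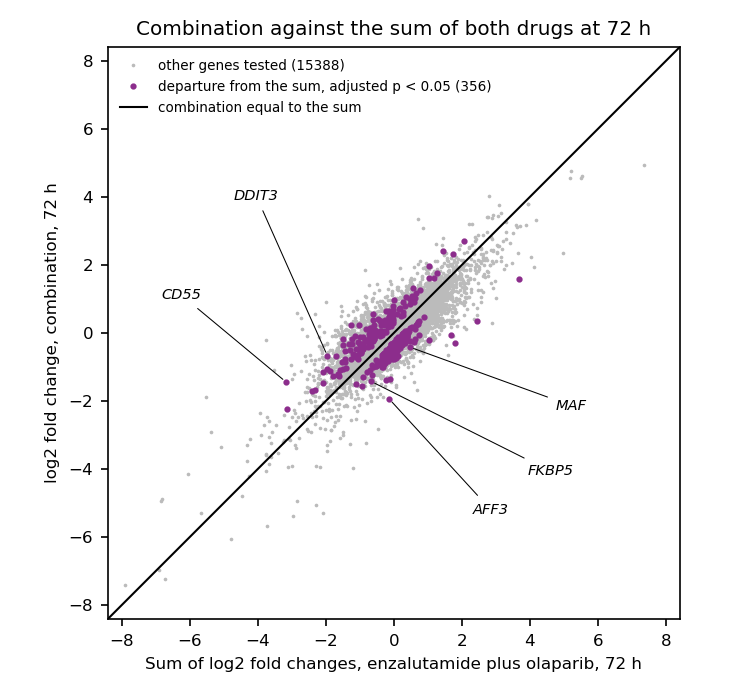
The log2 fold change of the combination at 72 h against the sum of both single-drug log2 fold changes for 15744 genes, with the 356 departing genes marked. Both axes share the same 3 DMSO libraries.

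How the effects changed from 8 h to 72 h was asked for each drug. The fall of KLK3 with enzalutamide deepened by 5.79 ± 0.18 (3 cultures in each of 4 groups, adjusted p 1.1e-24), while AOC1 gained 4.68 ± 0.58 (adjusted p 2.4e-07) and DEGS2, a sphingolipid enzyme gene that shares exons with EVL, 3.38 ± 0.54 (adjusted p 2.6e-05). The enzalutamide effect on 705 genes moved up and on 903 down. The olaparib effect moved up for 682 and down for 846, with DIO3, a deiodinase gene, up by 2.12 ± 0.39 (adjusted p 3.0e-04), CDKN1A up by 0.42 ± 0.09 (adjusted p 0.0015) and CRLS1 down by 4.31 ± 0.48 (adjusted p 5.1e-08). CRLS1 also rose in the DMSO cultures between 8 h and 24 h, so its DMSO level at 8 h enters this value. The effect of both drugs moved up for 1612 and down for 1992, with KLK3 down by 5.84 ± 0.19 (adjusted p 6.3e-24). A fit of only the libraries compared gave 673, 427 and 2053 genes rather than 1608, 1528 and 3604, and the olaparib count was 1012 without DMSO 8 h replicate 1 and 2421 without DMSO 72 h replicate 2.

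How untreated cultures changed was asked with DMSO alone. Between 8 h and 24 h CRLS1 rose from 0.968 ± 0.307 to 7.98 ± 1.42 CPM (2.94 ± 0.29, 3 cultures each, adjusted p 5.4e-08) and TAF10 by 1.83 ± 0.28 (adjusted p 1.5e-04), with 88 genes higher and 14 lower. Between 8 h and 72 h PLOD2, a collagen-modifying enzyme gene, rose from 0.368 ± 0.122 to 3.61 ± 0.645 CPM (3.29 ± 0.72, adjusted p 0.010), with 323 genes higher and 119 lower, and LDHB fell by 0.77 ± 0.13 (adjusted p 0.0012). PLOD2 lost its call with 2 of the libraries left out. The androgen-induced gene KLK3 was not called at either hour (0.16 ± 0.10 and 0.22 ± 0.10, adjusted p 0.61 and 0.19). Both counts leaned on single libraries. The first, 102, was 20 without DMSO 8 h replicate 1, 50 without DMSO 24 h replicate 1 and 67 without DMSO 8 h replicate 2, and 228 with no filter. The second, 442, was 19 without DMSO 8 h replicate 1, 47 without DMSO 8 h replicate 2, 58 without DMSO 72 h replicate 1, 919 without DMSO 8 h replicate 3 and 2116 without DMSO 72 h replicate 2, and it was 3 in a fit of only the libraries compared, 86 without the 3 libraries that stood apart and 874 with no filter.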

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

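The tests of a difference between times on 4 gene lists were chosen after the list counts had been seen, and the tests on single genes were planned. The effect of enzalutamide on DNA replication genes rose by 0.45 from 24 h to 72 h (camera adjusted p 6.9e-07 over 12 tests), that on mitotic genes by 0.50 (adjusted p 5.8e-06) and that on homologous recombination genes by 0.25 (adjusted p 0.0017). For the same 3 lists in that order the change was not called with olaparib, at -0.078, 0.084 and -0.087 (adjusted p 0.16, 0.27 and 0.50), or with both drugs, at -0.097, 0.17 and -0.0069 (adjusted p 0.18, 0.15 and 0.94). The effect on unfolded protein and amino acid response genes moved by -0.65 with enzalutamide (adjusted p 4.6e-08), -0.64 with olaparib (adjusted p 1.2e-07) and -0.87 with both (adjusted p 1.2e-08). Among single genes, effects that differed between 8 h and 72 h numbered 1608 for enzalutamide, 1528 for olaparib and 3604 for both. With enzalutamide these included AOC1 (4.68), DEGS2 (3.38), CCDC80 (3.20) and KLK3 (-5.79). With olaparib CCDC141 moved by 3.24, the steroid synthesis gene CYP11A1 by 2.30 and DIO3 by 2.12, against -4.31 for CRLS1, -3.32 for the hormone gene FGF21 and -3.30 for LRRC26. The CRLS1 value includes its low level in DMSO at 8 h, from which it rose in DMSO by 24 h. With both drugs AOC1 moved by 4.36, the antigen presentation gene HLA-DRA by 3.61 and DEGS2 by 3.20, against -5.84 for KLK3 and -5.43 for KLK2. The effect of one drug differed by the presence of the other at 72 h for 356 genes, including CD55 (1.73), VPS37D (1.49), RNF128 (1.31), DDIT3 (1.28) and KANK3 (1.28) above the sum, and ADAMTS3 (-2.10), RFX6 (-2.08), AFF3 (-1.81), TMCC3 (-1.72) and DOK3 (-1.25) below it.

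The exchange of labels was planned before the counts were seen. Each comparison of 2 groups had 10 divisions of its libraries, too few for a share below 0.05. The real division gave the largest count in each of them but DMSO at 72 h against 8 h. The real and the highest other counts at 8, 24 and 72 h were 375 and 7, 3402 and 0, and 1956 and 0 for enzalutamide, 72 and 11, 259 and 1, and 639 and 0 for olaparib, and 646 and 10, 4295 and 0, and 4199 and 0 for both drugs against DMSO. They were 93 and 0, 678 and 2, and 2913 and 0 for the combination against enzalutamide, and 255 and 3, 2665 and 0, and 5980 and 0 against olaparib. DMSO at 24 h against 8 h gave 114 and 1, and DMSO at 72 h against 8 h gave 3 where another division gave 12, so that 2 of 10 were as large.

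The 100 divisions shuffled libraries over all groups of a comparison and so mixed treatments or hours within a group. Mixing can raise the spread within groups or carry a drug effect into another contrast. The shares of 100 in this paragraph therefore do not test a departure, correlation or change on its own. With 100 divisions, the departure from the sum at 72 h gave 63 genes against a highest other of 0 (1 of 100 as large). At 8 h and 24 h it gave 0, and all 100 were as large, up to 127 and 11 genes. The enzalutamide correlations at 8, 24 and 72 h were 0.332, 0.696 and 0.789 with highest others of 0.246, 0.503 and 0.637 (1 of 100 each). The olaparib correlation at 8 h was 0.251 with a highest other of 0.258 (2 of 100), while those at 24 h and 72 h, 0.266 and 0.502, were reached by 12 and 7 of 100, up to 0.473 and 0.800. A division that mixed libraries with and without enzalutamide could carry that drug's effect into these correlations. The shares therefore neither exclude chance nor point to it. Effects that changed from 8 h to 72 h numbered 673 for enzalutamide, with a highest other of 1075 (3 of 100), 427 for olaparib, with 125 (1 of 100), and 2053 for both, with 2755 (2 of 100).

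The tests of this pattern were chosen after the 356 departing genes had been seen, and those genes were picked for the pattern. Their median departure at 72 h, signed by direction, was 0.481. It was 0.443 (SE 0.0196) without DMSO 72 h replicate 1 and 0.420 (SE 0.0209) when DMSO 24 h took the place of DMSO 72 h. Each SE here and below is the error over cultures of the genes' mean log2 CPM, not of the median beside it. Without DMSO 72 h replicate 1 it rests on fewer DMSO cultures and is itself uncertain. Because the genes were picked for the departure, these medians decide nothing. The fit without the 3 libraries that stood apart, of which only that library was in this comparison, called 412 genes, 283 of them among the 356. This argued against that library as the cause for those 283. Over the 356 genes a change in the DMSO cultures between 24 h and 72 h cannot be excluded as the cause. For the 89 genes of the replication and mitotic lists, which were fixed before the counts were seen, the median departure was -0.439. Without that library it was -0.420 (SE 0.0290), which argued against the library for these lists, and the lists moved by -0.00333 (SE 0.0215) in DMSO from 24 h to 72 h, which argued against a change in the DMSO cultures for them. An interaction of both drugs in the cells stays open as the biological reading.

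The fall of unfolded protein and amino acid response genes in all 3 drug groups at 72 h, with list medians of -0.456, -0.672 and -0.780, was also weighed with tests chosen after it was seen. Without DMSO 72 h replicate 1 the medians were -0.367 (SE 0.0105), -0.572 and -0.655. Shares of 0.805, 0.850 and 0.839 of the falls remained, which argued against that library as the main cause. A rise in the DMSO cultures from 24 h to 72 h, at 0.0578 (SE 0.0535), could not be told apart from no rise, so a part of the falls stays open. As the whole of the falls it was argued against, since the drug groups at 72 h lay below DMSO at 24 h by -0.381 (SE 0.0220), -0.631 and -0.586. No test separated a drug response from a state of the cultures, such as cell density, that came with the drugs.

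The fall of 89 replication and mitotic genes at 24 h of enzalutamide was larger than at 72 h, with pooled medians of -0.53 and -0.04. At 72 h the median was -0.15 for the replication genes, 15 of which were still lower, and -0.01 for the mitotic genes. This was weighed over both lists pooled, with tests chosen after it was seen. DMSO 72 h replicate 1 was argued against, as the 72 h median was -0.0435 (SE 0.0242) without it. A fall in the DMSO cultures was argued against as well, since their change from 24 h to 72 h was -0.00333 (SE 0.0215) where the enzalutamide cultures rose by 0.487. A return of cells to division under enzalutamide stays open, and cell numbers were not analysed here.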

How the results depend on the processing

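The counts of all 23 comparisons stayed within 1.5 times under RLE scaling, DESeq2, the stricter filter and lane as a block, and no result reversed. With no filter, olaparib at 8 h gave 428 genes, the combination against enzalutamide at 8 h 174, the departures at 8 h and 24 h 20 and 31, and DMSO at 24 h and 72 h against 8 h 228 and 874, where more genes were tested. In a fit of only the libraries compared, which has fewer residual degrees of freedom, enzalutamide at 72 h gave 1956, olaparib at 8 h and 72 h 72 and 639, the combination at 72 h 4199, the combination against enzalutamide at 24 h 678, the departure at 72 h 63, the changes from 8 h to 72 h 673, 427 and 2053 for enzalutamide, olaparib and both, and DMSO at 72 h 3. Fewer degrees of freedom alone do not account for the falls. Such fits raised enzalutamide at 24 h from 2960 to 3402, and the combination against enzalutamide at 72 h from 2283 to 2913. Replicate pairs with DMSO 72 h replicate 1 had a chi-square per degree of freedom of 13.6 and 21.2, against at most 5.35 in other pairs. Of the other libraries that stood apart, olaparib 8 h replicate 1 reached 5.34 and combination 8 h replicate 3 reached 4.20. The pair of enzalutamide 8 h replicates 1 and 3, which were kept, had 4.23, so this measure set only DMSO 72 h replicate 1 clearly apart. The fit of all libraries shares 1 spread per gene, so its errors with DMSO at 72 h may be too small. Without the 3 libraries that stood apart olaparib at 8 h gave 401, DMSO at 72 h 86 and the departure at 72 h 412, of which 283 were shared, and the cause was not tested. With a library left out in turn, counts ranged over 282 to 470, 2145 to 2509 and 3510 to 4545 for enzalutamide at 8, 24 and 72 h, 104 to 231, 100 to 123 and 1829 to 3525 for olaparib, 595 to 912, 2693 to 2850 and 5578 to 6585 for both drugs, 60 to 79, 121 to 280 and 1535 to 1909 for the combination against enzalutamide, and 249 to 300, 1522 to 1700 and 4367 to 4872 against olaparib. They ranged over 0 to 0, 0 to 6 and 193 to 879 for the departure, 1225 to 2411, 1012 to 2421 and 2850 to 4163 for the changes from 8 h to 72 h, and 20 to 1.2e+02 and 19 to 2116 for DMSO at 24 h and 72 h. Correlations ranged over 0.212 to 0.284, 0.594 to 0.641 and 0.660 to 0.739 for enzalutamide and 0.135 to 0.194, 0.176 to 0.222 and 0.370 to 0.450 for olaparib. Of 324 list tests 118 were called, against 183 with fry and 124 without the 3 libraries, a preset correlation added 47 calls and RLE scaling ended 2. Of 1033 calls of named genes 174 were lost under at least 1 alternative and 243 with a library left out.

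The replicate numbers did not pair the cultures. Same-numbered libraries deviated together with a mean correlation of -0.0174, 0.00668 and -0.00631 at 8, 24 and 72 h, and 1 of 18 pairs exceeded 0.1 each time. A block of replicate number kept all 23 counts within 1.5 times and ended the list calls of androgen-repressed genes at 8 h, for enzalutamide and for the combination against olaparib, and of p53 target genes for the departure at 24 h.

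Depth limited low genes, since a count of 0 bounded a level at 0.193 to 0.723 CPM by library.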

Other observations

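The mean share of counts from mitochondrial genes at 72 h was 6.43 ± 0.154% with olaparib, 6.84 ± 0.184% with both drugs and 5.18 ± 0.180% with enzalutamide, against 3.69 ± 2.03% in DMSO. The DMSO cultures had 1.54%, 5.56% and 3.97%, and the second lay above all 3 enzalutamide cultures (5.06% to 5.39%). At 24 h the shares were 5.11 ± 0.560%, 5.69 ± 0.265% and 5.91 ± 0.544% in the same order, against 4.37 ± 0.394% in DMSO, and these shares were not tested.

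Lane 6 held the libraries with the lowest totals, with a median of 6.08 M counts, and all 3 libraries that stood apart were from it. These were DMSO 72 h replicate 1 with 4.66 M counts, olaparib 8 h replicate 1 with 4.15 M and combination 8 h replicate 3 with 5.39 M. No library was a copy of another, and the pair of replicates closest to counting noise had a chi-square per degree of freedom of 1.37.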
